A study of Mus musculus with 15 samples.

How the data were processed

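RNA of 5 mouse fibroblast sources was measured on 15 Agilent 2-colour gene expression arrays, 3 arrays per source and 1 array per slide. Per the labels, the Cy5 channel held the fibroblast RNA and the Cy3 channel held a commercial mouse reference RNA on every array. The dyes were thus never swapped, and a dye effect common to all arrays drops out of a difference between sources. The labels call TAF-el4, TAF-tib42 and TAF-tib48 resistant and NSF and TAF-tib6 sensitive. The replicate numbers come from the labels, which do not say whether the 3 arrays of a source came from separate cultures or animals. P-values of comparisons between sources therefore measure the spread between arrays, which may be technical.

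The deposited scanner files hold, per the file headers, spot intensities for each dye as a mean signal and a median local background. They also hold the scanner software's own background-subtracted and LOWESS-normalised log10 ratio of Cy5 to Cy3, per the file headers. The headers and the submitters' processing notes name Agilent Feature Extraction 8.5.1.1, whereas a protocol label names version 9.5. The table of processed values deposited by the authors holds log2 ratios. Each of its columns followed the log2 of the scanner's ratio of the same array with a slope and a correlation of 1.0, so its direction is Cy5 over Cy3. The medians of its columns lay between 0.0337 and 0.0511, so they had not been set to 0, and 619 to 1075 of its cells were empty per array.

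The spot intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp with an offset of 50) and normalised within each array by loess. Control spots had weight 0 in the loess and were then removed, spots with an outlier flag were left out, saturated spots were kept, and spots of 1 probe were averaged. Of 41174 probes, 22207 were named through an accession in a reference table of assembly GRCm38.p6, 1157 through the description or the gene name column of the files, and 17810 kept the name in the files. Mela was named from its description. The table served for names, and coordinates are not reported. The probes carried 33574 names, of which 16847 were gene symbols and 5304 of these had several probes. The probe with the highest mean intensity over the 15 arrays stood for its gene. A gene was tested if its Cy5 signal was well above background, by the scanner's flag, on all 3 arrays of at least 1 source, which left 31277 genes. This flag is lenient: 89.7% to 95.8% of the Cy5 probes of an array carried it.

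Median Cy5 intensity per array lay between 174.7 and 285.9 against a median Cy5 background of 52 to 56, and the number of arrays limits the precision. The log2 ratios of arrays of 1 source correlated over genes at 0.9603 to 0.9876, and those of different sources at 0.8423 to 0.9485. The median SD of a gene between arrays of a source was 0.063 on the log2 scale.

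Pairs of sources were compared in 1 limma fit (lmFit, eBayes) of all 15 arrays with a mean per source. The resistant and sensitive sources were compared by limma on the 5 source means, so that the source and not the array was the unit. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Genes called in the same direction in several comparisons against 1 control source were counted beside the overlap of independent lists. Gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. List members were counted as called over all genes and as adjusted over the list alone.

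The groups, tests, 33 lists, alternatives and naming rule were fixed before the data were examined. Of the lists, 23 hold functional groups, 9 hold markers of other cell types (macrophage, lymphocyte and lymphoma, endothelial, pericyte and smooth muscle, keratinocyte and epithelial, adipocyte, skeletal muscle, melanocyte, nerve and Schwann) and 1 holds sex-linked genes. The rule named, for resistant against sensitive sources and for TAF-el4 against TAF-tib6, the 10 highest and 10 lowest log2 differences among called genes whose groups did not overlap, and 5 and 5 for the other comparisons. Clone, RIKEN, predicted and accession names were passed over. Where fewer than 10 genes qualified in a direction between resistant and sensitive sources, the places went to the largest differences among genes whose resistant means all lay on one side of both sensitive means. Up to 4 called members of each list described, and Pdgfc, Pdgfa and Vegfa everywhere, were named as well. A gene that the rule names is not reported here.

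The steps were tested on simulated data drawn from normal distributions with the means and spreads of the real genes. For TAF-el4 against TAF-tib6, 70% of 50 genes changed 1.2-fold, 98% of 50 changed 1.5-fold and 100% of 50 changed 2-fold were called among 31277 genes, with 8 false calls. For resistant against sensitive sources, 79.1% of 67 genes changed 2-fold, 95.5% of 67 changed 4-fold and 100% of 66 changed 16-fold were called, with 13 false calls. These shares hold for changed genes drawn at random from all genes. They also depend on the number of genes changed at once, because the Benjamini-Hochberg cut-off is more lenient when more genes pass. They do not say how often a change is called where few genes pass, or in genes that vary widely between sources. The shares for resistant against sensitive sources are thus not the power of the real comparison. In the real data 8 genes rose and 75 fell at least 2-fold with separated source means, but 1 gene was called. A shifted list was found in the simulated TAF-el4 comparison while 0 of the 32 other lists were called. The simulated genes were drawn independently, so this could not show false list calls that come from correlated genes.

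The alternatives set beforehand were median centring, quantile normalisation of average intensities, scaling of log ratios, the scanner's own ratios, the authors' table, no background subtraction, 2 other filters, averaged probes, kept outlier spots, each replicate or source left out, the replicate number as a block, fits on fewer arrays and other units of replication. Slide or scan day as a block could not be fitted, because each slide held 1 array and all arrays were scanned on 1 day. After the data were seen, the neighbouring slide numbers were found to form 3 runs of 5, called slide packs here. Pack 1 held NSF and 2 TAF-el4 arrays, pack 2 held 1 TAF-el4, 3 TAF-tib42 and 1 TAF-tib48 array, and pack 3 held 2 TAF-tib48 arrays and TAF-tib6. Slide pack as a block, comparisons within 1 pack, the Cy5 channel alone, and the omission of TAF-tib48 replicate 3 were added then.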

Results

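Gene expression was measured in mouse fibroblasts from 5 sources, each on 3 2-colour arrays against a common reference RNA, 15 arrays in all. TAF is read here, from the title of the series, as tumour-associated fibroblasts; EL4 is the name of a mouse T-cell lymphoma line, and the meaning of the other names is not given in the sources used here. TAF-el4, TAF-tib42 and TAF-tib48 are resistant sources per the labels (9 arrays), and NSF and TAF-tib6 are sensitive sources (6 arrays). That title ties these words to tumours refractory to treatment against VEGF, a growth factor of blood vessels. Values are log2 ratios of a source to the reference, and differences between them are log2 fold changes. Median Cy5 intensity per array lay between 174.7 and 285.9 over a background of 52 to 56. Of 31277 genes tested, the first principal component held 36.9% of the variance and the second 22.1%.

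The comparison of resistant with sensitive sources asks which genes go with the response named in the labels in more than a single pair of sources. Mela, described on the array as a melanoma antigen, was 30.9-fold higher in the resistant sources, with a log2 difference of 4.95 (SE 0.196, adjusted p = 0.0411). Its log2 ratio was 0.61 ± 0.32 (SD, n = 3 sources) in the resistant and -4.34 ± 0.14 (SD, n = 2 sources) in the sensitive sources, and a single probe measured it. Its adjusted p was 0.0568 with scaled log ratios and 0.0662 without background subtraction. Mela was the 1 gene called by limma, while 2882 genes had an unadjusted p under 0.05. Without TAF-el4 11 genes were called, and without NSF, TAF-tib42, TAF-tib48 or TAF-tib6 0 genes were.

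Several single genes, among them complement genes, the chemokine Cxcl12 and matrix genes, lay lower in each resistant source than in both sensitive sources, without a call. The complement list itself did not pass its test in this comparison. C3, the central complement component, differed by -3.01 (SE 0.446, adjusted p = 0.257), but its second probe differed by -0.05. Cxcl12, the ligand of Cxcr4, differed by -2.91 (SE 0.504, adjusted p = 0.261). Gas6, a ligand of the receptor Axl, differed by -2.58, the oxysterol hydroxylase Cyp7b1 by -2.28 and the proteoglycan Dcn by -2.21. The acute phase protein Hp (-2.15), the growth factor binding protein Igfbp2 (-2.13), the matrix protein Mgp (-1.95), the collagen receptor Itga11 (-1.83) and the complement protease C1s1 (-1.80) followed. In the other direction lay Xlr, an X-linked gene first known from lymphocytes, at 2.06 (SE 0.795, adjusted p = 0.536) and the transporter Slc16a11 at 1.77 (SE 0.265, adjusted p = 0.257). The prostaglandin synthase Ptgs1 (1.21), Olfr1221 (0.93), Chchd10 (0.90), Eno3 (0.83), Hoxa10 (0.83), Hoxa7 (0.81) and Bcar3 (0.81) followed, none of them called. Pdgfc, a ligand of the PDGF receptors, differed by 0.76 (SE 0.171, adjusted p = 0.344), Pdgfa by 0.33 (adjusted p = 0.5) and Vegfa by -0.08 (adjusted p = 0.882). Over all genes, 4251 had each resistant mean above both sensitive means and 4085 below, 26.7% of 31277 against 20% by chance.

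**Figure D1:**
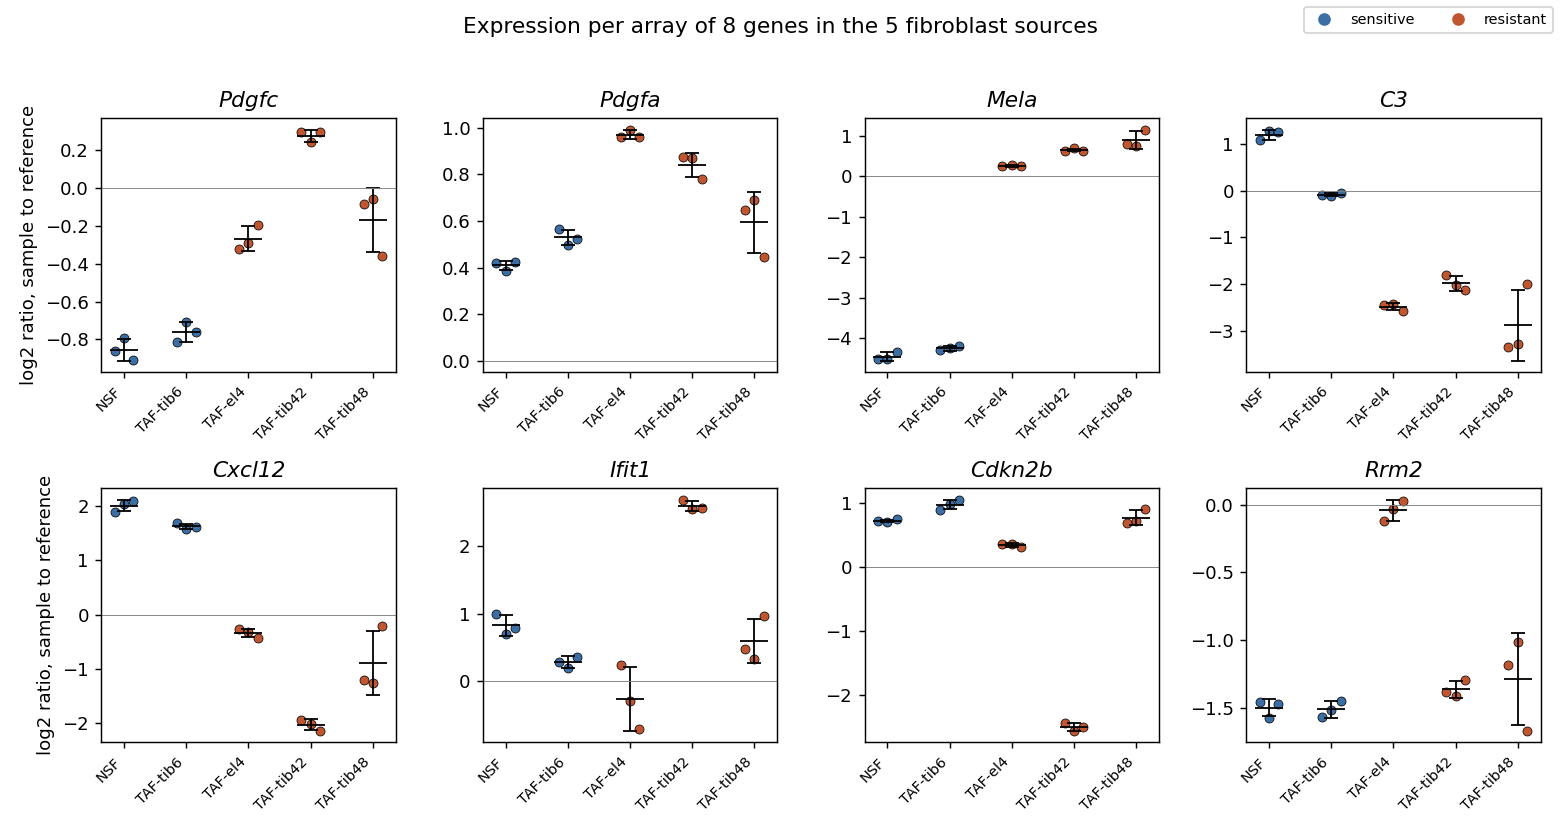
Log2 ratio of sample to reference on the y axis for 8 genes in the 5 sources; points are arrays, lines and bars give the mean ± SD (n = 3), blue marks sensitive and orange resistant sources. Mela lay at -4.45 and -4.24 in NSF and TAF-tib6 and between 0.26 and 0.90 in the resistant sources, whereas Ifit1 and Cdkn2b set TAF-tib42 apart.

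No member of any of the 33 lists was called between resistant and sensitive sources. The 44 cell cycle genes had a mean of 0.39 (6 rose when adjusted over the list alone; adjusted p = 1.4e-17), and adjusted p = 0.483 with an estimated correlation. The 36 matrix glycoproteins and proteoglycans had a mean of -0.50 (2 fell when adjusted over the list alone; adjusted p = 2.4e-06), and adjusted p = 0.301 with an estimated correlation. The 21 collagens had a mean of -0.39 (adjusted p = 2.1e-04), and adjusted p = 0.448 with an estimated correlation. Matrix proteases and inhibitors, lipid and sterol synthesis, angiogenic ligands, chemokines and inflammatory cytokines, and fibroblast position and lineage regulators lay lower at adjusted p = 0.0032 to 0.0441, and at adjusted p = 0.448 to 0.631 with an estimated correlation. Angiogenic ligands (scanner's ratios and authors' table), position and lineage regulators (scaled log ratios) and matrix proteases and inhibitors (Cy5 alone) lost this call at adjusted p = 0.057 to 0.0726. The other 25 lists had adjusted p = 0.0594 to 0.995.

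Each resistant source was also compared with TAF-tib6, the sensitive source whose name carries TAF as well. Among the genes named, TAF-el4 differed most in Ifi202b and Mela. Mela rose by 4.50 (SE 0.077, adjusted p = 4.5e-17). The prolactin-like proliferins Prl2c5 and Prl2c3 rose by 2.72 and 2.68 (SE 0.137 for both), although their probes may not tell these similar genes apart. Slc16a11 rose by 2.01, the immediate early transcription factors Egr2 and Egr1 by 1.97 and 1.90, the peptide hormone Cck by 1.73, the ribonucleotide reductase subunit Rrm2 by 1.47, Phlda1 by 1.44 and thrombomodulin (Thbd) by 1.42. The interferon-inducible gene Ifi202b fell by 4.71 (SE 0.089, adjusted p = 1.3e-16). The matricellular Ccn3 fell by 3.323 (SE 0.145). The neutrophil chemokines Cxcl1 and Cxcl5 fell by 2.78 and 2.72, lipoprotein lipase (Lpl) by 2.75, the proteoglycan Ogn by 2.72, the acute phase gene Saa3 by 2.67, C3 by 2.40, Pdgfrl by 2.32 and Cyp7b1 by 2.19. The second probe of C3 differed by 0.03. Pdgfc rose by 0.49 (SE 0.0644, adjusted p = 1.5e-05) and Pdgfa by 0.44 (adjusted p = 5.6e-06), and with slide pack as a block they differed by 0.44 (adjusted p = 0.0586) and 0.35 (adjusted p = 0.0848). Vegfa fell by 0.26 (adjusted p = 6.4e-04), with adjusted p = 0.136 after median centring.

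In this comparison 6442 genes were called, 3554 higher and 2888 lower in TAF-el4, of which 73 and 77 changed at least 2-fold. With slide pack as a block 1723 genes were called, and 145 of the 150 genes changed at least 2-fold kept their call. Without replicate 1 of every source 4241 genes were called. Cell cycle genes rose as a group: 41 of 44 rose and 1 fell (41 and 2 adjusted over the list alone; mean 0.72, adjusted p = 3.7e-30), with Rrm2 followed by Cdc20 (1.34), Cenpa (1.21) and Kif20a (1.15); this had adjusted p = 0.131 with an estimated correlation. Immediate early and heat shock genes rose in 18 of 26 (mean 0.40, adjusted p = 8.7e-06), among them Fosl1 (0.91), and myofibroblast and contractile genes in 16 of 23 (mean 0.17, adjusted p = 1.7e-05), among them Cnn1 (0.85); both had adjusted p = 0.131 with an estimated correlation. Of 21 collagens 12 fell (mean -0.35, adjusted p = 8.7e-06; adjusted p = 0.131 with an estimated correlation), led by Col6a1 (-1.21) and Col8a2 (-1.12). Matrix glycoproteins and proteoglycans fell in 18 of 36, led by Ogn, Dcn (-1.72) and Aspn (-1.72), at a mean of -0.37 (adjusted p = 8.7e-06; adjusted p = 0.244 with an estimated correlation). Interferon response (mean -0.15) and the Wnt pathway (mean -0.19) lay lower at adjusted p = 0.0033 and 0.012, and adjusted p = 0.483 and 0.188 with an estimated correlation. Complement, antigen presentation, angiogenesis inhibitors, Notch and Hedgehog pathways, lipid and sterol synthesis, TGF-beta signalling and targets and adipocyte lists passed at adjusted p = 0.0069 to 0.0441, but at adjusted p = 0.131 to 0.244 with an estimated correlation and 0.078 to 0.347 with slide pack as a block. After median centring lipid and sterol synthesis had a mean of -0.044 (adjusted p = 0.261). The Wnt pathway and TGF-beta signalling and targets lost the call with the scanner's ratios and the authors' table, adipocyte markers without background subtraction, and the Notch, TGF-beta, lipid and adipocyte lists with Cy5 alone, at adjusted p = 0.0583 to 0.128.

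TAF-tib42 differed from TAF-tib6 in interferon genes, cell cycle inhibitors and Cxcl12. Mela rose by 4.90 (SE 0.077, adjusted p = 5.3e-18), Xlr by 2.67 (SE 0.0601), the interferon-induced Ifit1 by 2.32 (SE 0.171), the endosomal GTPase Rab7b by 2.28 and the matrix protein Vit by 2.15. The ribosomal protein paralogues Rpl39l and Rps4l fell by 4.90 (SE 0.103) and 3.49 and Cxcl12 by 3.66 (SE 0.174). Ifi202b fell by 4.72 and Gas6 fell by 3.59. The second probe of Rpl39l differed by -1.38. Pdgfc rose by 1.04 (SE 0.0644, adjusted p = 7.7e-10), which is 2.05-fold. Pdgfa rose by 0.31 (adjusted p = 2.0e-04), and differed by 0.23 with slide pack as a block (adjusted p = 0.166), and Vegfa had no call (-0.08, adjusted p = 0.252).

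For TAF-tib42, 7761 genes were called, 3642 higher and 4119 lower, of which 83 and 181 changed at least 2-fold; the Cy5 channel alone gave 5363 higher and 4225 lower. With slide pack as a block 3046 were called, and 259 of the 264 genes changed at least 2-fold kept their call. Without replicate 1 of every source 4911 genes were called. Of 37 interferon response genes 30 rose and 0 fell (the same adjusted over the list alone), at a mean of 0.95 (adjusted p = 6.0e-25; adjusted p = 0.0364 with an estimated correlation). Isg15 rose by 2.09 and Usp18 by 2.06. Of 24 p53 targets and cell cycle inhibitors 13 fell (13 adjusted over the list alone; mean -0.62, adjusted p = 1.5e-06; adjusted p = 0.0364 with an estimated correlation), with Cdkn2b at -3.49, Cdkn2a at -2.93 and Zmat3 at -1.52. TGF-beta signalling and targets fell in 16 of 33 genes (20 adjusted over the list alone; mean -0.38, adjusted p = 2.6e-06; adjusted p = 0.0061 with an estimated correlation), with Id1 at -2.39 and Ltbp2 at -1.50. Axon guidance ligands and receptors fell in 14 of 33 (mean -0.20, adjusted p = 0.0028; adjusted p = 0.0364 with an estimated correlation), with the receptor Epha4 at -2.09, or -0.61 by another probe. Cell cycle (27 of 44 rose, mean 0.23), matrix glycoproteins and proteoglycans (21 of 36 fell, mean -0.48) and collagens (11 of 21 fell, mean -0.45) passed at adjusted p = 7.9e-07 to 1.2e-05, but at adjusted p = 0.184 to 0.389 with an estimated correlation. Hypoxia and glycolysis lay higher (mean 0.14) and Wnt, myofibroblast and contractile, angiogenic ligand, and matrix protease and inhibitor lists lower at adjusted p = 2.2e-04 to 0.0194, and at adjusted p = 0.184 to 0.28 with an estimated correlation. The macrophage markers (mean 0.10) and position and lineage regulators passed at adjusted p = 0.0199 and 0.0269, and at adjusted p = 0.225 and 0.0924 with an estimated correlation; with slide pack as a block both calls were lost (adjusted p = 0.156 and 0.164). Scaled log ratios also ended the calls of these lists, of matrix proteases and inhibitors and of myofibroblast and contractile genes, at adjusted p = 0.0877 to 0.228. Cy5 alone ended those of the proteases and the macrophage markers (adjusted p = 0.304 and 0.37), and median centring that of the macrophage markers (adjusted p = 0.0772).

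TAF-tib48 had lower chemokines and inflammatory cytokines than TAF-tib6 as a group. Mela rose by 5.14 (SE 0.077, adjusted p = 4.5e-18), Xlr by 2.65, the water channel Aqp1 by 2.62, Vit by 2.60 and Prl2c3 by 2.51. Rpl39l fell by 4.68 (SE 0.103), Saa3 by 3.70 (SE 0.255), Cxcl5 by 3.27, tissue factor (F3) by 3.01 and Hp by 3.67 (SE 0.441, adjusted p = 5.0e-06). The second probe of Rpl39l differed by -1.43. Hp varied widely between the TAF-tib48 arrays (-0.21 ± 1.56, SD, n = 3). Pdgfc rose by 0.59 (SE 0.0644, adjusted p = 1.6e-06) and Vegfa fell by 0.41 (adjusted p = 3.6e-06). Pdgfa had no call (0.06, adjusted p = 0.42), but without TAF-tib48 replicate 3 it rose by 0.14 (adjusted p = 0.0299).

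For TAF-tib48, 7719 genes were called, 3586 higher and 4133 lower, of which 56 and 177 changed at least 2-fold; within the slide pack that holds both sources 6638 genes were called. Without replicate 1 or 2 of every source 4964 and 4681 genes were called. Of 40 chemokines and inflammatory cytokines 17 fell and 3 rose (18 and 3 adjusted over the list alone; mean -0.57, adjusted p = 5.6e-07; adjusted p = 0.0135 with an estimated correlation), with Cxcl1 at -2.91, Cxcl14 at -2.61 and Cxcl12 at -2.52. Cell cycle genes rose in 27 of 44 (mean 0.33, adjusted p = 3.0e-10; adjusted p = 0.28 with an estimated correlation), and Ccnd1 rose by 1.18. Collagens fell in 13 of 21 (mean -0.46, adjusted p = 4.8e-07; adjusted p = 0.0738 with an estimated correlation), with Col8a1 at -1.87, and matrix glycoproteins and proteoglycans in 21 of 36 (mean -0.55, adjusted p = 1.5e-06; adjusted p = 0.28 with an estimated correlation), with Ogn at -2.61. Lipid and sterol synthesis, p53 targets and cell cycle inhibitors, angiogenic ligands, adipocyte markers, TGF-beta signalling and targets and antigen presentation lay lower at adjusted p = 1.3e-04 to 0.02, and at adjusted p = 0.0738 to 0.28 with an estimated correlation. Endothelial markers lay higher (mean 0.15, with Emcn at 1.79), and position and lineage regulators and the Wnt pathway lower, at adjusted p = 0.0242 to 0.0477. These last 3 had adjusted p = 0.0738 to 0.28 with an estimated correlation and 0.0507 to 0.0867 with slide pack as a block. Each of them also lost the call with the scanner's ratios (adjusted p = 0.0732 to 0.174) and the authors' table. Scaled log ratios ended it for the Wnt pathway and the regulators, Cy5 alone for the endothelial markers, and omission of the background subtraction or of the filter for the Wnt pathway, at adjusted p = 0.0502 to 0.131.

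The 3 comparisons with TAF-tib6 shared 2008 genes called in 1 direction, 892 higher and 1116 lower in each resistant source. Independent lists of these sizes would share 47.4 and 50.3 genes, but the comparisons share the TAF-tib6 arrays and part of the excess may come from that. With slide pack as a block 552 genes were shared, after median centring 1328, and without replicate 1 or 2 of every source 1107 and 1172. After Mela, the weakest of the 3 differences was 1.40 for Ptgs1, 1.17 for Slc16a11, 1.05 for the transcription factor Foxf2, 0.92 for Osbpl3 and 0.85 for Hoxa7. It was -2.19 for Cyp7b1, -2.08 for Ifi202b, -1.98 for Gas6, -1.97 for Cxcl12, -1.91 for Ccn3, -1.89 for the Wnt antagonist Dkk2 and -1.45 for Dcn. The shared genes include some that set TAF-tib6 apart from NSF too, and these do not go with the response. Ifi202b and Dkk2 were higher in TAF-tib6 than in NSF, and TAF-tib48 had more Ifi202b than NSF.

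**Figure D2:**
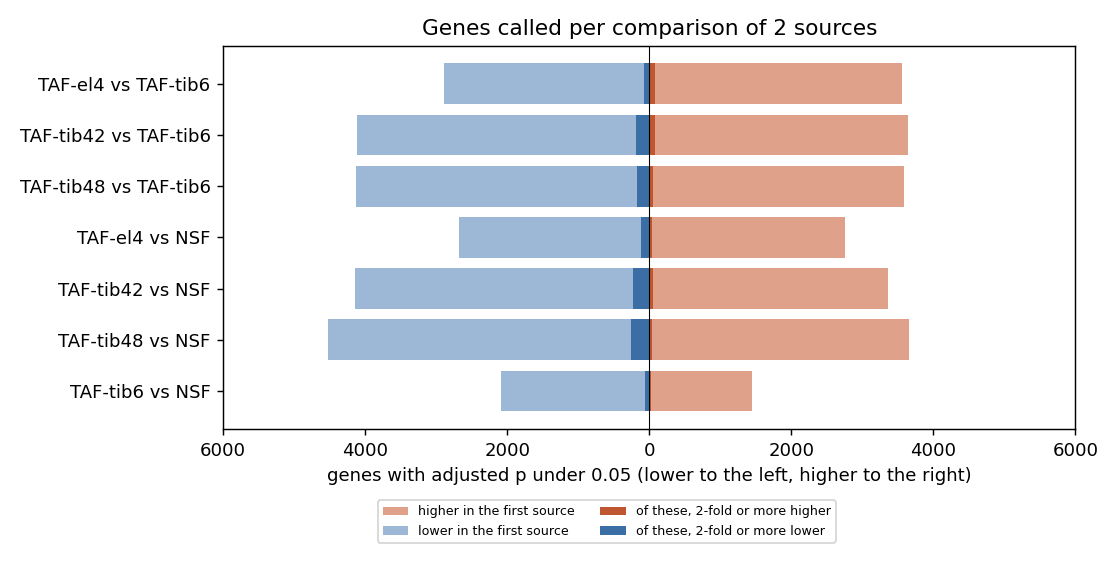
Number of genes called on the x axis for the 7 comparisons between sources on the y axis, lower to the left and higher to the right; dark parts changed at least 2-fold. TAF-tib48 against NSF had 8182 called genes and TAF-tib6 against NSF 3544.

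Each resistant source was compared with NSF, the sensitive source whose name does not carry TAF. TAF-el4 lay lower in complement and in chemokines and inflammatory cytokines as groups. Saa3 fell by 3.92 (SE 0.255, adjusted p = 3.5e-09), C3 by 3.69 (SE 0.22), Cxcl1 by 3.50 (SE 0.117), Saa1 by 3.25 and Dcn by 3.03. Second probes of C3 and Saa1 differed by -0.09 and -0.12. Mela rose by 4.71 (SE 0.077, adjusted p = 2.1e-17), Prl2c5 by 2.61, Prl2c3 by 2.50, Slc16a11 by 2.39 and connexin 26 (Gjb2) by 2.28. The second probe of Gjb2 differed by 0.29. Pdgfc rose by 0.59 (adjusted p = 2.2e-06) and Pdgfa by 0.56 (adjusted p = 3.4e-07), and Vegfa had no call (0.07, adjusted p = 0.393).

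Here 5432 genes were called, 2751 higher and 2681 lower, of which 33 and 115 changed at least 2-fold. Median centring gave 1729 higher and 2953 lower. The scanner's ratios, the authors' table, scaled log ratios and the Cy5 channel alone also gave more lower than higher genes (2068 lower and 1773 higher for Cy5), and the slide pack that holds both sources gave 4605 calls. Complement fell in 9 of 17 genes (9 adjusted over the list alone; mean -0.80, adjusted p = 1.6e-08; adjusted p = 0.0047 with an estimated correlation), with C1s1 at -2.36, C1ra at -1.84 and Cfb at -1.80. Lipid and sterol synthesis fell in 12 of 22 (mean -0.22, adjusted p = 9.6e-09; adjusted p = 0.0063 with an estimated correlation), with Fdps at -0.51. Chemokines and inflammatory cytokines fell in 13 of 40 (mean -0.39), angiogenesis inhibitors in 9 of 21 (mean -0.35), growth factor receptors in 8 of 22 (mean -0.21) and position and lineage regulators in 10 of 39 (mean -0.10), each at adjusted p = 0.0293 with an estimated correlation. Among the receptors Flt1 fell by 1.54. Cell cycle genes rose in 41 of 44 (mean 0.64, adjusted p = 1.8e-31; adjusted p = 0.091 with an estimated correlation). Matrix glycoproteins and proteoglycans fell in 23 of 36 (mean -0.44, adjusted p = 5.7e-12; adjusted p = 0.108 with an estimated correlation) and interferon response in 18 of 37 (mean -0.29, adjusted p = 2.4e-07; adjusted p = 0.193 with an estimated correlation). Collagens, matrix proteases and inhibitors, Wnt, angiogenic ligands and myofibroblast and contractile genes passed at adjusted p = 1.9e-04 to 0.0358, and at adjusted p = 0.172 to 0.396 with an estimated correlation; the myofibroblast and contractile genes had adjusted p = 0.0777 with slide pack as a block, 0.282 after median centring (mean 0.044, against 0.104) and 0.0602 and 0.0608 with the scanner's ratios and the authors' table. Angiogenic ligands lost the call with these ratios and table and with Cy5 alone, and matrix proteases and inhibitors with Cy5 alone, at adjusted p = 0.0913 to 0.13.

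TAF-tib42 showed higher interferon genes and lower Cxcl12 against NSF too. Mela rose by 5.10 (SE 0.077, adjusted p = 5.2e-18), Xlr by 3.07 (SE 0.0601), the ubiquitin-like Isg15 by 2.001 (SE 0.17), its protease Usp18 by 1.82 and Ifit1 by 1.77. Cxcl12 fell by 4.04 (SE 0.174), Igfbp2 by 3.96 (SE 0.077), Rpl39l by 3.91, Rps4l by 3.45 and Gas6 by 3.40. The second probe of Rpl39l differed by -0.79. Pdgfc rose by 1.13 (SE 0.0644, adjusted p = 2.2e-10) and Pdgfa by 0.43 (adjusted p = 5.6e-06). Vegfa rose by 0.25 (adjusted p = 7.3e-04), with adjusted p = 0.335 after median centring.

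In this pair 7500 genes were called, 3356 higher and 4144 lower, of which 47 and 236 changed at least 2-fold. Median centring gave 2958 higher and 5719 lower, slide pack as a block gave 2426 calls, with 278 of the 283 genes changed at least 2-fold kept, and omission of replicate 1 or 2 of every source gave 4547 and 4885. Interferon response rose in 30 of 37 genes (30 adjusted over the list alone; mean 0.81, adjusted p = 2.5e-23; adjusted p = 0.0255 with an estimated correlation). TGF-beta signalling and targets fell in 19 of 33 (20 adjusted over the list alone; mean -0.54, adjusted p = 1.2e-07; adjusted p = 0.0023 with an estimated correlation), with Id1 at -2.91 and Fst at -2.71. P53 targets and cell cycle inhibitors fell in 15 of 24 (mean -0.57, adjusted p = 3.1e-07; adjusted p = 0.0199 with an estimated correlation), with Cdkn2b at -3.23 and Cdkn2a at -2.14. Complement (10 of 17 fell), position and lineage regulators (15 of 39), axon guidance ligands and receptors (12 of 33), chemokines and inflammatory cytokines (17 of 40), angiogenic ligands (13 of 29) and matrix proteases and inhibitors (15 of 32) lay lower, at adjusted p = 0.0131 to 0.035 with an estimated correlation. Among the ligands Vegfd fell by 1.79, Angptl4 by 1.74 and Vegfc by 1.59. Matrix glycoproteins and proteoglycans fell in 24 of 36 (mean -0.55, adjusted p = 6.6e-12; adjusted p = 0.0717 with an estimated correlation). Myofibroblast and contractile, collagen, cell cycle, immediate early and heat shock, hypoxia and glycolysis, antigen presentation, Wnt, angiogenesis inhibitor, lipid and sterol synthesis and growth factor receptor lists passed at adjusted p = 1.7e-06 to 0.0093, and at adjusted p = 0.0535 to 0.424 with an estimated correlation. The lymphocyte and lymphoma markers and the macrophage markers passed at adjusted p = 0.0163 and 0.0428, and at adjusted p = 0.143 and 0.184 with an estimated correlation; with slide pack as a block they had adjusted p = 0.0678 and 0.56. The mean of the hypoxia and glycolysis list changed sign after median centring (-0.002), and that of the macrophage markers with scaled log ratios (-0.001). Median centring also ended the calls of cell cycle (mean 0.029, adjusted p = 0.125), antigen presentation (0.055) and both marker lists (0.125 and 0.251). Scaled log ratios ended those of growth factor receptors (adjusted p = 0.0614) and lymphocyte and lymphoma markers (0.568). The macrophage markers also lost the call without background subtraction, without the filter and with Cy5 alone, and the lymphocyte and lymphoma markers with Cy5 alone, at adjusted p = 0.0599 to 0.135.

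TAF-tib48 lay lower than NSF in chemokines and inflammatory cytokines as a group. Saa3 fell by 4.95 (SE 0.255, adjusted p = 5.5e-11), C3 by 4.08 (SE 0.22), Saa1 by 3.75 (SE 0.184), Rpl39l by 3.69 and Cxcl1 by 3.63. Second probes of C3, Saa1 and Rpl39l differed by -0.20, -0.11 and -0.85. Mela rose by 5.35 (SE 0.077, adjusted p = 2.3e-18), Xlr by 3.04, Ifi202b by 2.76, Prl2c3 by 2.32 and Prl2c5 by 2.30. Pdgfc rose by 0.69 (SE 0.0644, adjusted p = 2.0e-07). Pdgfa rose by 0.18 (adjusted p = 0.0143), but differed by 0.06 after median centring (adjusted p = 0.6) and by 0.25 with slide pack as a block (adjusted p = 0.228). Vegfa had no call (-0.08, adjusted p = 0.237), but fell by 0.20 after median centring (adjusted p = 0.0475) and differed by 0.09 with slide pack as a block.

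Between TAF-tib48 and NSF 8182 genes were called, 3659 higher and 4523 lower, of which 43 and 260 changed at least 2-fold. Median centring gave 2372 higher and 5393 lower, slide pack as a block gave 2036 calls, with 301 of the 303 genes changed at least 2-fold kept, and omission of replicate 1 or 2 of every source gave 5412 and 4674. Chemokines and inflammatory cytokines fell in 20 of 40 genes (24 adjusted over the list alone; mean -0.70, adjusted p = 3.1e-08; adjusted p = 0.0037 with an estimated correlation), with Il6 at -3.57 and Cxcl5 at -3.45. Lipid and sterol synthesis fell in 15 of 22 (16 adjusted over the list alone; mean -0.33, adjusted p = 7.5e-10; adjusted p = 0.0037 with an estimated correlation), with Hmgcs1 at -0.84. TGF-beta signalling and targets fell in 17 of 33 (mean -0.42; adjusted p = 0.0158 with an estimated correlation), position and lineage regulators in 12 of 39 (mean -0.21; adjusted p = 0.0285 with an estimated correlation), with Twist1 at -2.06. Endothelial markers rose in 8 of 19 and fell in 2 (mean 0.13; adjusted p = 0.0449 with an estimated correlation), with Emcn at 1.79 and Flt1 at -1.06. Matrix glycoproteins and proteoglycans fell in 21 of 36 (mean -0.62, adjusted p = 7.5e-10; adjusted p = 0.117 with an estimated correlation), cell cycle genes rose in 22 of 44 (mean 0.25, adjusted p = 3.6e-08; adjusted p = 0.333 with an estimated correlation) and collagens fell in 14 of 21 (mean -0.41, adjusted p = 9.1e-07; adjusted p = 0.0796 with an estimated correlation). Angiogenic ligands, complement, myofibroblast and contractile genes, matrix proteases and inhibitors, immediate early and heat shock genes, Hox genes, lymphocyte and lymphoma markers, p53 targets and cell cycle inhibitors and angiogenesis inhibitors passed at adjusted p = 5.8e-04 to 0.0472, and at adjusted p = 0.0514 to 0.249 with an estimated correlation. The mean of the lymphocyte and lymphoma markers changed sign with slide pack as a block (-0.022), and without TAF-tib48 replicate 3 they had adjusted p = 0.0676. With scaled log ratios these markers, angiogenesis inhibitors, matrix proteases and inhibitors, myofibroblast and contractile genes and p53 targets and cell cycle inhibitors lost the call at adjusted p = 0.0724 to 0.584. Cy5 alone ended it for the last 3 of these, for Hox genes and for immediate early and heat shock genes (adjusted p = 0.0674 to 0.171). The p53 targets and angiogenesis inhibitors also lost it with the scanner's ratios and the authors' table (adjusted p = 0.0504 to 0.135), the inhibitors without the filter (0.082), and the p53 targets and lymphocyte markers without background subtraction (0.0603 and 0.0543).

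The sensitive sources were compared with each other, which gives the difference between sources of 1 response. TAF-tib6 had more Ifi202b than NSF by 4.83 (SE 0.089, adjusted p = 1.7e-16). Brinp3 rose by 1.91, Lpl by 1.90 (SE 0.137), Dkk2 by 1.82 and Pdgfrl by 1.76. Syt13 fell by 2.68, while its second probe differed by 0.13. The activin-binding protein Fst fell by 2.14 (SE 0.0941), Ch25h, which hydroxylates cholesterol, by 1.96 (n = 2 arrays of NSF) and Aqp1 by 1.88. Pdgfc (0.09, adjusted p = 0.392) and Pdgfa (0.12, adjusted p = 0.16; -0.05 after median centring) had no call. Vegfa rose by 0.33 (adjusted p = 1.0e-04), with adjusted p = 0.0875 after median centring.

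Between the sensitive sources 3544 genes were called, 1451 higher and 2093 lower in TAF-tib6, of which 25 and 59 changed at least 2-fold. Median centring gave 6156 calls, slide pack as a block gave 425, with 73 of the 84 genes changed at least 2-fold kept, and omission of replicate 1, 2 or 3 of every source gave 1653, 2115 and 2335. Complement fell in 9 of 17 genes (10 adjusted over the list alone; mean -0.43, adjusted p = 3.3e-05; adjusted p = 0.0253 with an estimated correlation), with Serping1 at -1.49 and Cfb at -1.31. Lipid and sterol synthesis fell in 9 of 22 (11 adjusted over the list alone; mean -0.14, adjusted p = 6.6e-05; adjusted p = 0.0345 with an estimated correlation). Adipocyte markers rose in 3 of 14, Lpl, Fabp4 (0.55) and Pparg (0.31), at a mean of 0.25 (adjusted p = 0.0011; adjusted p = 0.0345 with an estimated correlation), but had a mean of 0.165 with slide pack as a block (adjusted p = 0.127). The second probe of Fabp4 differed by 0.06. Immediate early and heat shock genes fell in 11 of 26 (mean -0.31, adjusted p = 3.3e-05; adjusted p = 0.0542 with an estimated correlation), with Egr1 at -1.35 and Fos at -1.23. Myofibroblast and contractile genes, lymphocyte and lymphoma markers, growth factor receptors, TGF-beta signalling and targets, chemokines and inflammatory cytokines, matrix proteases and inhibitors, interferon response and p53 targets and cell cycle inhibitors passed at adjusted p = 0.003 to 0.049, and at adjusted p = 0.0542 to 0.626 with an estimated correlation. Of these, growth factor receptors, TGF-beta signalling and targets, matrix proteases and inhibitors and interferon response had adjusted p = 0.0624 to 0.857 with slide pack as a block. With Cy5 alone TGF-beta signalling and targets, chemokines and inflammatory cytokines, interferon response, matrix proteases and inhibitors and myofibroblast and contractile genes (mean -0.011, against -0.068) had adjusted p = 0.173 to 0.343. The call also ended for chemokines and inflammatory cytokines after median centring, for interferon response with the scanner's ratios and the authors' table, for matrix proteases and inhibitors with scaled log ratios, and for p53 targets and cell cycle inhibitors with each of these and without the filter, at adjusted p = 0.0509 to 0.992. The mean of the list of p53 targets and cell cycle inhibitors changed sign after median centring (-0.043) and with slide pack as a block (-0.018), and that of the lymphocyte and lymphoma markers with slide pack as a block (-0.062). In none of these 8 comparisons did the list tests of collagen cross-linking genes, of the markers of pericytes and smooth muscle, keratinocytes and epithelium, skeletal muscle, melanocytes and nerve and Schwann cells, or of the sex-linked genes pass. Single members were called in each of these lists but the sex-linked one; 8 of 16 cross-linking genes fell and 2 rose in TAF-tib48 against NSF.

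The 4 TAF sources shared 688 genes called in 1 direction against NSF, 121 higher and 567 lower, where independent lists would share 1.6 and 3.44. The NSF arrays are common to these comparisons, and part of the excess may come from that. With slide pack as a block 132 genes were shared, after median centring 1084, and without replicate 1 or 2 of every source 388 and 428. The weakest of the 4 differences was 1.32 for C1qtnf12, 0.80 for Hoxc9, 0.71 for Fyb and 0.69 for Gcnt1. It was -1.58 for Ch25h, -1.50 for the basement membrane protein Nid2, -1.41 for the growth factor Ptn and -1.37 for the complement inhibitor Serping1.

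**Figure D3:**
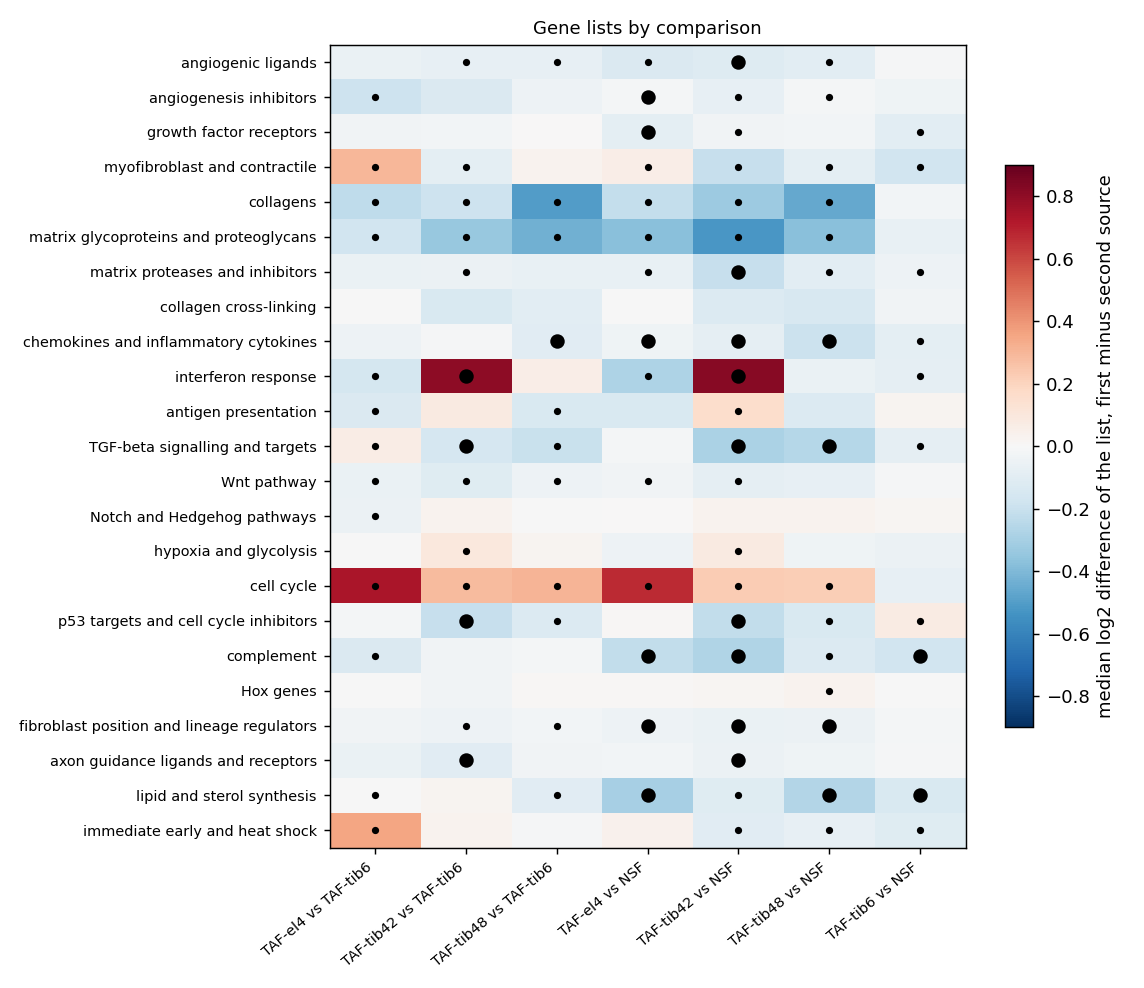
Median log2 difference (colour) of 23 functional gene lists (y axis) in the 7 comparisons between sources (x axis); small dots mark lists with an adjusted p under 0.05 at the preset correlation and large dots those that also passed with an estimated correlation. The interferon list stands out in TAF-tib42, with means of 0.95 against TAF-tib6 and 0.81 against NSF.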

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

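The tests of slide packs, scalings, cell mixtures and TAF-tib48 replicate 3 given here were chosen only after the results were seen, although the scalings and background settings themselves were set beforehand.

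In 132 tests, each TAF source was set against the mean of the 3 others for every list, and 6 of these tests, on 5 lists, passed at adjusted p under 0.05 both at the preset and with an estimated correlation. Interferon response was higher in TAF-tib42 by 0.91 (adjusted p = 1.3e-34; 0.0319 with an estimated correlation). TGF-beta signalling and targets were higher in TAF-el4 by 0.34 (adjusted p = 1.9e-06; 0.00977 with an estimated correlation) and lower in TAF-tib42 at -0.32 (adjusted p = 1.1e-08; 0.00447 with an estimated correlation). In TAF-tib48, chemokines and inflammatory cytokines lay lower at -0.41 (adjusted p = 1.1e-07; 0.0112 with an estimated correlation), lipid and sterol synthesis lower at -0.19 (adjusted p = 1.3e-06; 0.0285 with an estimated correlation) and endothelial markers higher at 0.22 (adjusted p = 1.9e-05; 0.0148 with an estimated correlation).

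Mela was higher in the 3 resistant sources. A difference between slide packs is argued against by the values within 1 pack, 4.713 for TAF-el4 against NSF and 5.193 for TAF-tib48 against TAF-tib6 (SE 0.0871 for both). The lowest difference over the scalings and background settings in 6 comparisons was 4.399, so the size of the difference does not come from these steps. RNA of lymphoma cells among the fibroblasts stays open. Against TAF-tib6, 0 of 18 lymphocyte and lymphoma markers rose in any resistant source. The highest upper 95% bound of their mean was 0.103, in an interval over markers taken as independent. Against NSF, 1 of 18 rose in TAF-el4, 5 in TAF-tib42 and 8 in TAF-tib48, and 4 in TAF-tib6, where Mela is low too. The level of Mela in such cells was not measured. A single probe measured Mela, so a sequence difference could also give this pattern if the sources differ in mouse strain. Whether they do is not known here, and this was not tested.

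Interferon genes were higher in TAF-tib42. Within its slide pack, against 1 TAF-el4 and 1 TAF-tib48 array, the mean of the list was higher by 1.018, with 31 of 34 members higher. This argues against a difference between packs. The 95% interval of 0.748 to 1.287 runs over list members taken as independent. The members are correlated, so it is too narrow and does not measure the spread between arrays. Over the scalings and background settings the lowest mean was 0.769. The mean of the macrophage markers was higher by 0.097 against TAF-tib6 and by 0.076 against NSF. That of the interferon list was higher by 0.947 and 0.809. These means argue against RNA of macrophages as the full explanation. The 95% bounds also run over genes taken as independent, with upper bounds up to 0.233 for the markers and lower bounds of 0.716 and 0.619 for the interferon list. Lyz2 fell by 0.68 against TAF-tib6 while Tyrobp rose by 0.64. Against NSF Lyz2 fell by 0.323 while Tyrobp rose by 0.733 and Ctss by 0.244, so a small share of macrophages stays open. An interferon response of these fibroblasts may be a source of the pattern, but it was not tested; interferon levels in fresh cultures of the source would bear on it.

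TAF-tib48 replicate 3 lay apart from the other arrays of its source. It differed at least 2-fold from replicate 2, of the same slide pack, in 19 genes and from replicate 1 in 13, whereas replicates 1 and 2 differed in 1 and the 12 pairs of arrays of other sources in 0 to 4. Hp was higher in it by 2.69, Cpxm1 by 1.49, Cxcl5 by 1.38 and C3 by 1.31. Single bad spots are argued against by second probes, of which 24 of 28 (85.7%) deviated in the same direction (exact binomial test, two-sided, p = 0.00018). A mixture with RNA of 1 other source would give each gene the same share. The median share was 6.15% to 8.5% over the 4 other sources. Over genes, replicate 3 correlated with the TAF-tib6 arrays at 0.8943 to 0.9065, against 0.8462 to 0.8818 for replicates 1 and 2, as a mixture would give. With the NSF arrays the correlations were 0.88 to 0.8876 against 0.8423 to 0.8614, so the rise does not single out 1 source. With TAF-el4 they were lower, at 0.8744 to 0.8846 against 0.8863 to 0.8949, and with TAF-tib42 the ranges overlapped. The spread of the shares was at least 4.2 times that between replicates 1 and 2 for each of the 4 sources; for TAF-tib6 the share was 1.36% by Rpl39l and 31.4% by Cpxm1. These shares argue against a mixture as the full explanation; a small share beside another difference, or a different state of the cells of that replicate, may remain and was not tested.

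For each pair of sources the 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. The real split gave the numbers reported and was the 1 split with as many genes. The highest other split gave 0 genes, or 1 for TAF-tib6 against NSF. Every other split mixes both sources in each group, so a difference between sources widens the spread within groups. Few calls there were thus fixed in advance, and no conclusion is drawn from them. For resistant against sensitive sources, the 10 splits of the 5 sources are too few as well, with 1 gene in the real split and 0 as the highest of the others. The other splits there also mix responses within a group.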

How the results depend on the processing

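Slide pack as a block, comparisons within 1 pack, the Cy5 channel alone and the omission of TAF-tib48 replicate 3 were tests chosen only after the results were seen. Over the alternatives, 135 counts of genes stayed within 1.5 times the reported count, 29 fell and 7 rose beyond it. Values of lists and named genes were recomputed under the scalings, ratios and background settings, without the filter and with Cy5 alone. They were also recomputed under the slide pack settings and without TAF-tib48 replicate 3. They were not recomputed with averaged probes, the stricter filter, kept outlier spots or any other replicate or source left out. Nor were they under the replicate block, fits on fewer arrays or other units. Of list values 851 kept direction and call, 104 lost the call and 6 changed sign. The alternatives repeated the list test at the preset correlation only, so the calls with an estimated correlation were not rechecked. Among lists that had passed with it, only adipocyte markers for TAF-tib6 against NSF lost the preset call, with slide pack as a block (adjusted p = 0.127). Of values of named genes 1007 kept direction and call, 10 lost and 2 gained a call and 2 without a call moved. These totals include settings that nearly repeat each other, so they do not count independent checks. The authors' table holds the scanner's ratios, and comparisons within 1 pack gave nearly the same values as slide pack as a block. Called genes ranged from 1723 to 6968 for TAF-el4, 3046 to 9588 for TAF-tib42 and 4681 to 7777 for TAF-tib48 against TAF-tib6. Against NSF they ranged from 3840 to 6013, 2426 to 8677 and 2036 to 8337, and from 425 to 6156 for TAF-tib6. Shared genes ranged from 552 to 2265 against TAF-tib6 and from 132 to 1084 against NSF.

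Slide pack as a block gave 1723, 3046, 2426, 2036 and 425 calls where sources lay in different packs, and 552 and 132 shared genes. By construction, the few sources with arrays in 2 packs then carry these comparisons. The lower precision alone reduces the calls, so the drop does not measure a difference between packs. Median centring gave 6156 calls for TAF-tib6 against NSF and 1328 and 1084 shared genes; the cause was not tested. With a replicate left out, fewer arrays lowered the counts. For replicates 1, 2 and 3 in turn they were 4241, 4484 and 4843 (TAF-el4), 4911, 5271 and 6139 (TAF-tib42) and 4964, 4681 and 6559 (TAF-tib48) against TAF-tib6. Against NSF they were 3848, 3840 and 4352, 4547, 4885 and 6284, 5412, 4674 and 6773, and 1653, 2115 and 2335 for TAF-tib6. Shared genes were 1107, 1172 and 1548, and 388, 428 and 482. Without TAF-tib48 replicate 3, 7691 genes were called against TAF-tib6, 7683 against NSF, and 2265 and 732 were shared.

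For resistant against sensitive sources, the 1 call became 0 with scaled log ratios, without background subtraction, and without NSF, TAF-tib42, TAF-tib48 or TAF-tib6, and 11 without TAF-el4. With the spread between arrays in place of that between sources it became 8828, 8587 with the replicate number as a block, and 6045 with slide pack as a block; by construction these treat arrays of a source as replicates. With source as a random block, 1 correlation of 0.4 between arrays of a source served for every gene, and the count became 1473. By construction genes whose sources differ more than this correlation allows are called too easily. The 1473 calls are thus not a count with the source as the unit. Lists that changed sign were hypoxia and glycolysis for TAF-tib42 against NSF (-0.002, median centring), p53 targets and cell cycle inhibitors for TAF-tib6 against NSF (-0.043, median centring, and -0.018, slide pack as a block), macrophage markers for TAF-tib42 against NSF (-0.001, scaled log ratios) and lymphocyte and lymphoma markers against NSF with slide pack as a block (-0.022 for TAF-tib48, -0.062 for TAF-tib6); the cause was not tested.

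Replicate numbers do not pair the arrays: correlations of deviations were -0.194 to 0.168 for arrays of 1 number and -0.227 to 0.249 for others. Quantile normalisation of average intensities leaves log ratios as they are, tests nothing and is left out of the totals. Slide or scan day could not be fitted as a block. Median Cy5 signal of 174.7 to 285.9 over a background of 52 to 56 limits what dim genes can show.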

Other observations

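The values given here were chosen only after the results were seen, and no tests of an explanation were run on them. The neighbouring cell cycle inhibitor genes Cdkn2a and Cdkn2b were low in TAF-tib42 alone among the 5 sources, at log2 ratios of -1.94 and -2.51, against -0.27 to 0.99 and 0.35 to 0.98 in the others. Mtap, near them on the chromosome, differed from TAF-tib6 by -0.23 (adjusted p = 0.00777), Mdm2 by -0.78 (adjusted p = 5.1e-06) and Trp53 by 0.04 (adjusted p = 0.625).

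The signal of some probes was high or low by source, and a single probe measured Ifi202b. Whether the sources share a mouse strain is not known here, and a sequence difference between strains was not tested. Rpl39l lay at -3.09 and -2.86 in TAF-tib42 and TAF-tib48 and at 0.83 to 1.82 in the other sources, but its second probe differed by -1.38 and -1.43 between these and TAF-tib6. Xlr lay at -0.06 and -0.09 in the same sources and at -3.13 to -2.46 in the others, and its second probe differed in the same direction, by 2.18 and 2.13 from TAF-tib6 and by 2.71 and 2.65 from NSF. Ifi202b lay at -0.31 in TAF-tib6, -2.38 in TAF-tib48 and -5.14 to -5.01 in the other sources.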
